A study of Mus musculus with 4 samples.

How the data were processed

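Gene expression was measured in limb and brain of mouse embryos at embryonic day 13.5, in wild type (WT) embryos and in embryos with conditional ablation of Rest (CKO). Per the labels, Rest-floxed mice were given doxycycline from embryonic day 8.5 to 13.5, which switched on Cre recombinase in utero. The same doxycycline days are recorded for all 4 samples, WT included. Total RNA was extracted with the RNeasy Plus Mini kit, amplified and labelled with Cy3 as cRNA, per the labels' protocols. Each of the 4 groups had 1 array, so there were no replicates. Whether an RNA sample came from a single embryo or from several is not given in the sources used here.

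The arrays were scanned and quantified with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. The deposited values are intensities on a linear scale, and per the file headers each was background-subtracted and detrended within its own array, with no normalization between arrays. Spots that did not exceed background hold a substitute value in those files. The deposited series table held the same intensities rounded; its largest gap to the scanner files was 0.0071 on the log2 scale over 45018 spots. The raw mean and local background intensities that the authors deposited in the scanner files served the alternative background correction alone.

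Control spots were left out, and each array's 75th percentile of log2 signal over its remaining spots was subtracted. The spots of each of the 41174 probes were then averaged. All log2 values given are on this scale, on which 0 is the 75th percentile of the array. A probe counted as detected when the scanner software called it well above background. A gene was represented by its probe with the highest mean over the 4 arrays and entered a comparison when detected on at least 1 of its arrays. Where 1 of the pair was not well above background, the difference is a bound: the bright array's normalized log2 value against the dim array's lowest normalized signal among probes well above background, or against the probe's own signal where that was higher. Such differences are written "at least", and a bound that would point the other way was set to 0.

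Probes were named through their accession for 26933 of 41174 probes, through a current symbol for 5570 and through a synonym held by 1 gene for 894. The remaining 7777 kept the name in the file. This gave 27629 genes or unnamed transcripts, 20024 of them with a current symbol and 8918 with more than 1 probe. Probe positions are those of the scanner files on mm9. A current RefSeq table served names and gene order alone.

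Differences are CKO minus WT within a tissue, so a positive value is higher in CKO. With 1 array per group, CKO could not be tested against WT within a tissue, and calls there rest on size, at least 2-fold. A test over both tissues, added after the data had been examined, fitted genotype with tissue as a block in limma, with Benjamini-Hochberg adjustment, on genes well above background and not saturated on all 4 arrays. The only error the arrays give is technical, from 245 probes printed 10 times on each array. The median SD of a single spot's CKO minus WT difference was 0.10 log2 in limb and 0.098 in brain. It was 0.066 in limb and 0.062 in brain for bright probes, and 0.33 in limb and 0.36 in brain for dim ones. This error covers neither labelling nor differences between embryos, and the number of arrays limits the precision.

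A set of 30 gene lists was fixed before the data were examined, along with the comparisons, the settings and the rule for naming genes. The lists cover REST targets, REST cofactors, neuronal, glial and regional brain markers, limb, skeletal, muscle, skin, blood, vessel and immune markers, stress responses and control genes. The members of the REST-target neuronal list came from textbook knowledge of genes with a REST-binding element, not from these arrays. A list is described by the median difference of its detected members and by the central 95% of medians of 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. This describes these 4 samples and is not a test between groups. Another 2 lists, inner ear and peripheral sensory ganglion genes, were added after the differences had been seen.

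Named genes were Rest, the 10 genes with the largest difference in each direction among those detected and not saturated on both arrays and with no other well-measured probe moving the opposite way, and the 3 largest bounds in each direction. Each list also named up to 4 members with the largest difference of at least 1.5-fold on both arrays, and the REST-target neuronal list up to 8. Genes named beyond this rule were chosen after their values were seen. Brain-enriched and limb-enriched genes were those at least 8-fold different between the mean of both brain arrays and the mean of both limb arrays.

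Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The alternative background correction, normexp with an offset of 50, and the fit with tissue as a block used limma 3.58.1 in R 4.3.3. The steps were tested on simulated data. For the limb comparison, with 17440 genes, 50 of 50 genes raised 3-fold and 44 of 50 genes lowered 3-fold were called. At 8-fold, the limb simulation called 50 of 50 raised genes and 46 of 50 lowered genes. For the brain comparison, with 17818 genes, 50 of 50 genes raised 3-fold and 49 of 50 lowered 3-fold were called, and at 8-fold 50 of 50 raised and 45 of 50 lowered genes. None of the 17240 unchanged limb genes or 17618 unchanged brain genes was called in the simulation. Apart from the changed genes, both simulated arrays were the WT array plus the noise of repeated spots, with the WT floor. The simulation therefore gives no rate of false calls for arrays from different embryos or with unlike floors. For the limma fit with tissue as a block, simulated on 15630 genes with equal changes in both tissues, 44 of 50 genes raised 2-fold, 48 of 50 lowered 2-fold and 50 of 50 changed 8-fold in either direction were called, with 21 of 15430 unchanged genes. The noise in that simulation was assumed, not estimated from these arrays, and no change differed between tissues. It therefore checks the steps and gives no rate of detection for the fit on the real arrays.

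Alternatives tried were normexp, quantile normalization, a percentile over probes detected on all arrays, the series table, a filter on both arrays, no filter, the mean of a gene's probes, other size thresholds, other enrichment thresholds, a common floor for dim signals and support by another probe. A list of genes near a REST-binding motif was planned but not analysed here, because it needs a genome sequence. Spots the scanner software marked as uneven or as outliers were left out. There were 74 on the WT limb array, 71 on CKO limb, 82 on WT brain and 58 on CKO brain. A probe left without a spot on at least 1 array was dropped. The 2 saturated probes of each array were not among genes named by size.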

Results

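Expression was profiled by single-colour microarray in 4 samples, 1 each of WT limb, CKO limb, WT brain and CKO brain, all at the same embryonic day. All 4 arrays lay on 1 slide and were scanned on 1 day. Spots well above background made up 62.7% of the 43379 non-control spots on the WT limb array, 68.6% on CKO limb, 64.5% on WT brain and 70.7% on CKO brain. The 75th percentile of signal was 777 on WT limb, 925 on CKO limb, 900.4 on WT brain and 1001 on CKO brain. Control transcripts added at known amounts gave squared log-log correlations from 0.977 on WT limb to 0.987 on WT brain.

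The tissue labels were checked with the WT arrays. Pan-neuronal markers were higher in WT brain than in WT limb by a median of 18.4-fold, and REST-target neuronal genes by 19.5-fold. Skeletal muscle genes differed by a median of -6.59 log2 in WT brain against WT limb, tendon and connective tissue genes by -4.29 and limb patterning genes by -3.30. Xist, the RNA that coats the inactive X chromosome, was detected on all 4 arrays, at 3.45 in WT limb, 3.07 in CKO limb, 2.73 in WT brain and 2.54 in CKO brain. It alone was detected in the list of sex-linked genes, with a CKO minus WT difference of -0.37 in limb and -0.20 in brain. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were above background on none of them.

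Rest encodes a zinc-finger repressor that keeps neuronal genes silent in non-neuronal cells, and it is the gene the Cre alleles target. It was lower in CKO at all 3 of its probes in both tissues. At the probe on chromosome 5 from 77709928 to 77709987 (mm9), Rest was 15.6-fold lower in CKO limb and 11.9-fold lower in CKO brain, which left 6.39% and 8.40% of the WT signal. The probe from 77711857 to 77711916 was 17.1-fold lower in CKO limb, at 5.85% of WT. In CKO brain that probe was not above background and was at least 6.60-fold lower. The brightest on average, from 77715162 to 77715221, was 4.01-fold lower in CKO limb and 1.88-fold lower in CKO brain, so 24.9% and 53.3% of its WT signal remained. A probe outside the deleted part of a gene checks nothing, and the labels do not say which part of Rest is floxed. In WT samples, Rest measured by its first probe was at 2.41 in limb and -0.16 in brain.

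**Figure D1:**
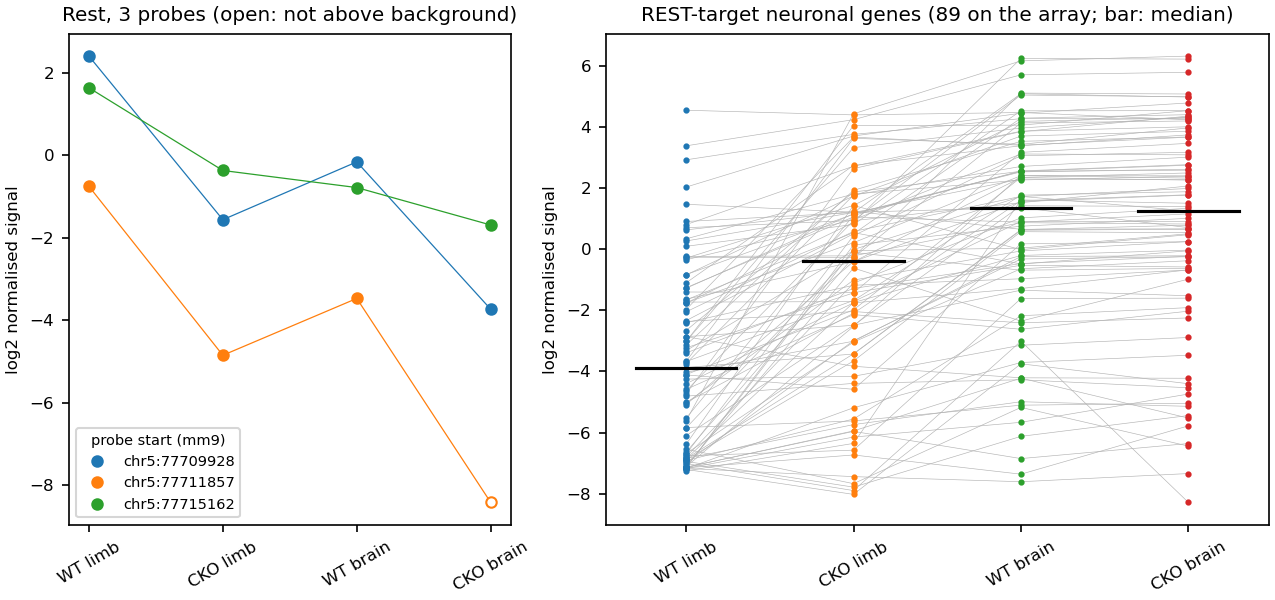
Left, log2 normalised signal of the 3 Rest probes on each of the 4 arrays. Right, log2 normalised signal of REST-target neuronal genes on each array (1 array per group), where the median lies at -3.87 in WT limb, -0.40 in CKO limb, 1.35 in WT brain and 1.25 in CKO brain.

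The first comparison asked which genes differ in limb, a largely non-neuronal tissue, when Rest is ablated. The largest differences measured on both arrays were those of chromogranin B (Chgb), 165-fold higher in CKO limb, from -4.73 to 2.64, chromogranin A (Chga), 157-fold higher, and secretogranin III (Scg3), 134-fold higher, all proteins of secretory granules. The splicing regulator Celf3 was 104-fold higher, Rundc3a 81.0-fold, Lrp11 71.6-fold and Sez6l2, a neuronal membrane protein, 49.8-fold. The postsynaptic exchange factor Iqsec3 was 48.4-fold higher, the mitochondrial gene Gdap1 45.5-fold and the neuronal vesicle gene Nrsn1 41.0-fold. Some genes without signal above background in WT limb were bright in CKO limb. The microtubule regulator Stmn3 was at least 664-fold higher, the neuronal adaptor subunit Ap3b2 at least 222-fold and the sialyltransferase St8sia3 at least 109-fold.

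Chgb, Chga, Scg3, Rundc3a, Sez6l2, Gdap1 and Stmn3 are members of the REST-target neuronal list, and Celf3, Lrp11, Iqsec3, Nrsn1, Ap3b2 and St8sia3 are not. Of its 92 members, 76 were detected in limb, and 54 of those were at least 2-fold higher and 0 lower. Their median difference was 2.06 log2 (4.16-fold), with quartiles of 0.80 and 4.03, against -0.08 to 0.01 for random lists. Further members were Gprin1, a neurite outgrowth gene, 33.4-fold higher, and the scaffold Mapk8ip2, 23.1-fold higher. Snap25, Cplx1 and Syp, which act at synaptic vesicles, were at least 66.3-fold, 47.3-fold and 23.3-fold higher. The glutamate receptor gene Gria2 was 5.42-fold higher, the neuronal tubulin Tubb3 6.21-fold and the microtubule gene Stmn2 7.17-fold. Synapsin I (Syn1) had discordant probes: its brighter probe differed by -0.15 and the other, dark in WT limb, by at least 2.24 log2. For the 54 members at least 2-fold higher, the level in CKO limb was a median of 2.61-fold below that in WT brain. At or above the WT brain level were 8 of them, among them Chga, Ptprn, Scg2, Sez6l2, Stx1a and Unc13a.

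Other gene groups with neuronal or regional functions differed less in limb. REST-target genes with functions outside neurons had a median of 0.67 in 10 detected members, above the random range of -0.26 to 0.17, and 4 were at least 2-fold higher. Among them, the natriuretic peptide gene Nppa was 5.01-fold higher and the pacemaker channel Hcn2 2.53-fold. Pan-neuronal markers, which share no member with the REST-target list, had a median of 0.32 in 24 detected genes, against -0.09 to 0.05 for random lists, and 4 were at least 2-fold higher. These were Crmp1 (9.61-fold), the neuronal nuclear antigen gene Rbfox3 (3.26-fold), Rtn1 (2.45-fold) and doublecortin (Dcx), whereas the difference was 0.06 for tau (Mapt) and 0.00 for Uchl1. The REST cofactor list had a median of -0.03, inside its random range, with Srrm4, a splicing factor of neurons, 5.19-fold higher.

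Midbrain and hindbrain regional genes had a limb median of 0.23 above the random range of -0.24 to 0.14, and the 4 members at least 2-fold higher were Hox genes: Hoxa2 by 4.07-fold, Hoxb5 by 3.11-fold, Hoxa5 by 2.72-fold and Hoxb4 by 2.68-fold. Monoaminergic and cholinergic genes had a median of 0.29 and eye genes one of 0.33, both above random lists, and neural progenitor markers one of 0.07, just above a limit of 0.069. The GABAergic median of 0.160 was just above a limit of 0.152, and it was -0.06 when genes had to be detected on both arrays and -0.02 with the mean of all probes. Somatostatin (Sst), in that list, was 3.67-fold higher and Gad2 at least 3.39-fold. Medians lay inside the random range for glutamatergic genes (-0.23), sensory neuron genes (0.00), Schwann cell and neural crest genes (0.06), forebrain genes (-0.12) and choroid plexus genes (0.00). Among glutamatergic genes, Neurod2 was 3.08-fold lower and Slc17a6 at least 7.76-fold higher.

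Red cell genes were lower in CKO limb, with a median of -1.06 log2 in 15 detected erythroid genes against -0.10 to 0.06 for random lists, and 8 of them at least 2-fold lower. The haem synthesis enzyme Alas2 was 3.46-fold lower, the red cell anion exchanger Slc4a1 2.84-fold, and the probe named for the globin gene Hba-a1, which has a near-identical copy, 2.23-fold. Epidermis genes had a median of -0.59 (random -0.09 to 0.05), with the keratin Krt4 3.25-fold lower and Krtdap 1.91-fold lower. Krt1 was 2.29-fold lower at its brighter probe, and its other probe differed by 0.01. Bone and joint genes had a median of -0.38, and 2 members were at least 2-fold lower: the type I collagen gene Col1a1 by 4.23-fold and the homeobox gene Dlx3 by 2.35-fold. Interferon response genes (-0.38; Rsad2 2.15-fold lower at its brighter probe), macrophage genes (-0.21; Pf4 1.75-fold lower), limb patterning genes (-0.21), tendon and connective tissue genes (-0.21), cartilage genes (-0.14; Epyc 2.69-fold lower) and immediate early genes (-0.11) also had medians below their random lists.

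Skeletal muscle genes were slightly higher in CKO limb. The median was 0.51 in 29 detected members, against -0.07 to 0.03 for random lists, with troponins Tnni1 1.57-fold and Tnnt2 1.55-fold higher and the myogenic factor Myog 1.54-fold. Hypoxia and glycolysis genes had a median of 0.39, against -0.11 to 0.06, with the vasodilator peptide gene Adm 1.72-fold, Egln3 1.65-fold and Bnip3 1.62-fold higher. Endothelial genes had a median of 0.05, at a limit of 0.054. Cell cycle genes (0.00), p53 targets (0.00) and housekeeping genes (-0.01) lay within the range of random lists.

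Genes with the largest difference in the opposite direction in limb shared no fixed list. Prl2c5 (proliferin family) was 48.4-fold lower in CKO limb, the transcript C130026L21Rik 44.0-fold, the trypsin inhibitor Spink1 23.2-fold and the phosphatase subunit Ppp1r3a 17.9-fold. Another probe of Ppp1r3a, not above background in WT limb, went the opposite way, by at least 0.41 log2. Dmrta2, a transcription factor of the developing forebrain, was 11.8-fold lower, Nudt12 9.29-fold, Prap1 7.46-fold and Map7d2 5.55-fold. The netrin receptor Unc5d was 10.1-fold lower at its brighter probe, and its second probe differed by -1.05. Gt(ROSA)26Sor, the transcript of a locus widely used for inserting transgenes, was 6.20-fold lower. Bounds on lower genes were at least 67.5-fold for the vomeronasal receptor Vmn2r26, 39.0-fold for the forebrain and eye gene Six3 and 36.5-fold for the oocyte gene Oog4. Vmn2r26 and Oog4 were bright on the WT limb array alone: Vmn2r26 was at 0.32 there and -7.59 in WT brain. Six3 was at -0.47 in WT limb and lower, at -3.31, in WT brain. Without replicates, an outlying spot on the WT limb array cannot be told from expression for these genes. Among 18449 genes compared in limb, 463 were at least 2-fold higher in CKO and 396 at least 2-fold lower. Measured on both arrays were 264 of the higher and 216 of the lower ones. Where a gene had another detected probe, that probe differed at least 1.5-fold the same way for 101 of 142 higher genes and for 12 of 34 lower genes.

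The second comparison asked the same of brain, which holds many neurons. REST-target neuronal genes differed little. The median of 87 detected members was 0.11 log2 (1.08-fold), above the -0.05 to 0.00 of random lists, with 1 member at least 2-fold higher and 3 at least 2-fold lower. The higher one was Ptprn, a protein of dense-core vesicles, by 2.59-fold. The lower ones were the serotonin receptor gene Htr1a by 2.47-fold, and, as bounds, the opioid receptor gene Oprm1 by at least 2.01-fold and the acetylcholine synthesis enzyme Chat by at least 9.05-fold. Among members under the 2-fold threshold, Chga differed by 0.54 log2, Chgb by 0.51 and Scg3 by 0.48, and the prohormone convertase gene Pcsk2 by -0.48. The AMPA receptor partner Cacng2 was 1.53-fold higher, and the kinase activator Cdk5r2 1.57-fold lower.

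Cartilage genes were higher in CKO brain than in WT brain. Their median difference was 1.95 log2 (3.88-fold) in 24 detected members, against -0.07 to 0.07 for random lists, and 15 were at least 2-fold higher and 0 lower. The cartilage collagen Col9a1 was 33.7-fold higher, chondromodulin (Cnmd) 17.1-fold, the proteoglycan aggrecan (Acan) 16.6-fold and Cytl1 10.1-fold. The type II collagen gene Col2a1 was 3.27-fold higher, epiphycan (Epyc) at least 24.2-fold and the link protein Hapln1 at least 15.8-fold. The difference that was largest of all genes measured on both brain arrays was that of Oc90, an otoconial protein of the inner ear, 105-fold higher. Otor, an inner ear and cartilage gene, was 7.09-fold higher, the fibrillar collagen Col5a3 10.9-fold, the iron-binding protein gene Meltf 9.34-fold, the calcium-binding granulocyte gene S100a9 7.51-fold and the matrix gene Smoc2 7.21-fold. Fam3b, dark in WT brain, reached -1.36 in CKO brain.

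Connective tissue genes had a brain median of 0.78 in 20 detected members (random -0.07 to 0.05), with 7 at least 2-fold higher. Examples are the mesenchymal transcription factors Foxc2 (3.18-fold), Twist2 (2.52-fold) and Twist1 (2.41-fold) and the type I collagen gene Col1a2 (2.10-fold). Col1a1, which encodes the partner chain of Col1a2, was lower, at -1.32 log2, and bone and joint genes as a list had a median of 0.02, inside the random range. Skeletal muscle genes had a median of 0.34 in 25 detected members, above -0.04 to 0.09, with the myosin genes Myl1 4.78-fold and Myh3 2.99-fold higher. Limb patterning genes had a median of 0.18, above random lists, with Msx2 and Prrx1 each 2.03-fold higher, although 1 further probe of Prrx1 differed by -0.31. Endothelial genes (median 0.26), macrophage and microglia genes (0.23, with the complement gene C1qa 1.55-fold higher), hypoxia and glycolysis genes (0.20) and immediate early genes (0.07, with Hspa1b 2.89-fold lower) were above random lists as well.

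Several brain lists pointed lower in CKO brain by small amounts. Glutamatergic neuron genes had a median of -0.33 (random -0.09 to 0.06). Forebrain regional genes had a median of -0.31, below their random lists. Neural progenitor markers (-0.21, with Neurog2 1.45-fold lower), GABAergic genes (-0.19) and REST cofactors (-0.10) were below their random lists. Pan-neuronal markers had a median of -0.06, within the random range of -0.08 to -0.01, and monoaminergic genes one of -0.09, within -0.09 to 0.11. Midbrain and hindbrain genes had a median of 0.19, above the random range, with Hoxc5 1.86-fold higher.

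Sensory neuron genes had a median of -0.15, below the -0.10 to 0.13 of random lists. The sensory neuron gene Avil was 4.14-fold lower and the sodium channel Scn9a at least 8.52-fold. Schwann cell and neural crest genes had a median of 0.14, above random lists, and -0.06 with the mean of all probes; Gfra3, a receptor subunit of sensory neurons, was 3.81-fold lower. Erythroid genes had a median of 0.08, above random lists, which became -0.09 with normexp and -0.03 with quantile normalization. Medians within the random range were those of choroid plexus (0.04, with Trpv4 2.23-fold higher), epidermis (0.01, with Epcam 4.61-fold higher), eye (0.00, with Pmel 2.04-fold higher), interferon (0.06), p53 target (0.00), cell cycle (-0.02), housekeeping (-0.00) and non-neuronal REST-target genes (0.07).

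**Figure D2:**
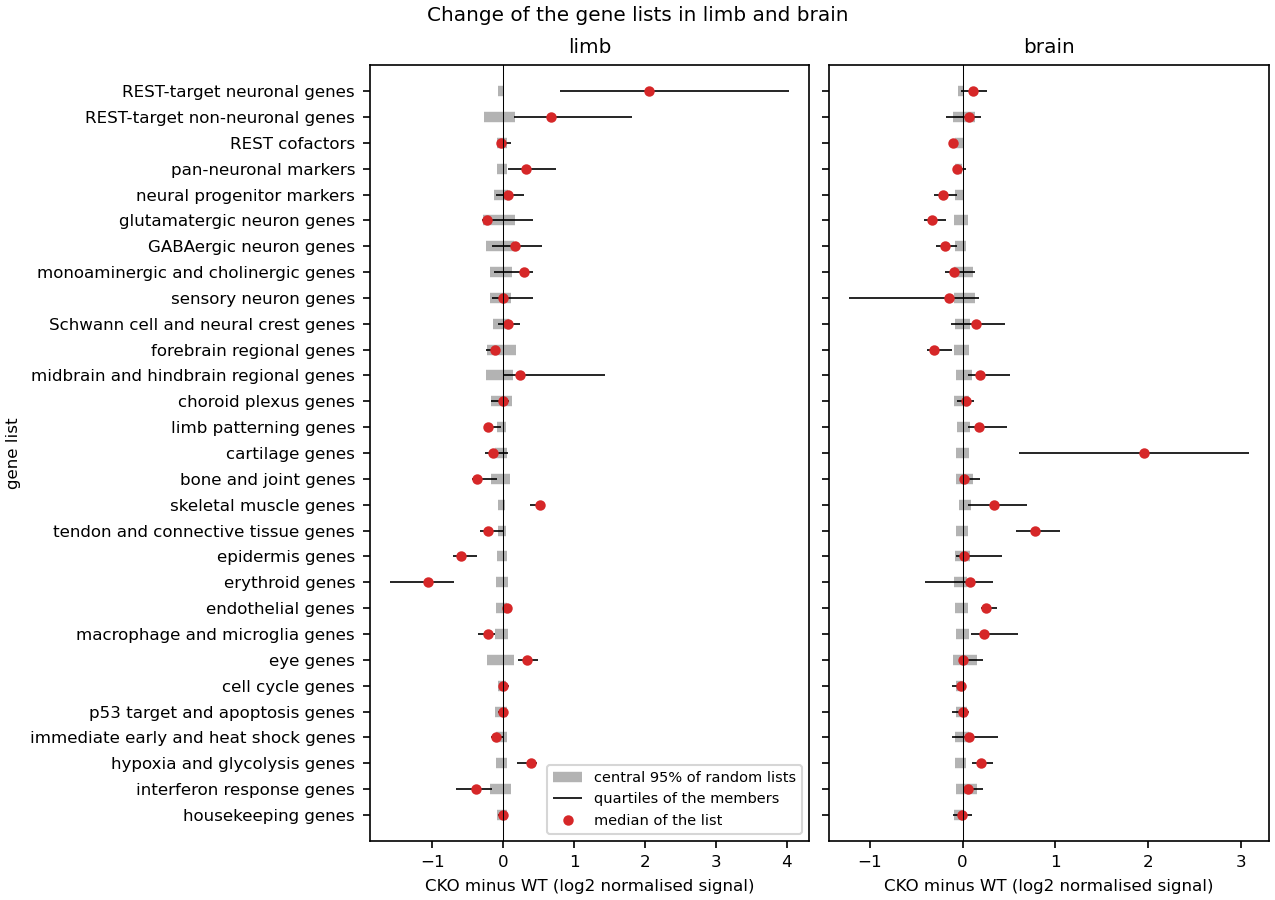
Median log2 difference of CKO against WT for each fixed gene list in limb and in brain (1 array per group), with the central 95% of matched random lists as bars. REST-target neuronal genes reach 2.06 in limb and 0.11 in brain, and cartilage genes -0.14 in limb and 1.95 in brain.

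Genes much lower in CKO brain were of varied kinds. The actin regulator Eps8l1 was 24.3-fold lower, the olfactory receptor Olfr338 21.9-fold, Spata17 21.7-fold and the fatty acid receptor Gpr84 18.7-fold. The death receptor gene Tnfrsf10b differed by -3.75 log2 at its brighter probe, but its other probes, detected in CKO brain and not in WT brain, showed no fall. The lens crystallin Crygc was 11.4-fold lower, Fbxo15 11.2-fold and Gm597 10.6-fold. The transporter Slc45a3 was 8.60-fold and the kinase Uhmk1 8.20-fold lower. The lectin Cd209a was at least 85.2-fold lower, the skeletal factor Nkx3-2 at least 79.1-fold and the lipid flippase Atp8b1 at least 71.9-fold. Eps8l1, Olfr338, Gpr84, Cd209a, Nkx3-2 and Atp8b1 were far brighter on the WT brain array than on any other. Cd209a was at 0.22 there and -6.71 in WT limb. Without replicates, an outlying spot cannot be told from expression for these genes. Of 18944 genes compared in brain, 260 were at least 2-fold higher in CKO, 151 of them measured on both arrays, and 231 at least 2-fold lower, 87 on both. Another detected probe differed at least 1.5-fold the same way for 24 of 56 higher genes and 5 of 18 lower genes.

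The tissues were then compared with each other, since the series title asks about derepression of neuronal genes. For the 76 REST-target neuronal genes detected in both, the limb difference minus the brain difference had a median of 1.88 log2, against -0.04 to 0.04 for random lists. It was positive for 70 of the 76 and at least 1 log2 for 53. The 463 genes at least 2-fold higher in CKO limb included 54 of the REST-target neuronal list. Of these 463, 405 were detected in brain, where their median difference was 0.18 (random -0.03 to -0.00); 318 of them (78.5%) were above 0 and 28 at least 2-fold higher. Outside the REST-target list the brain median of such genes was 0.17, with 77.8% above 0. Of the genes at least 2-fold lower in CKO limb, 181 were detected in brain, where their median was -0.00085, against 0.00 to 0.01 for random lists. That gap is far smaller than the technical SD of a difference. Above 0 were 31.5%, and the rest include any bound set to 0 as well as lower genes.

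Genes of the other tissue were shifted upward in each comparison. Brain-enriched genes had a median of 0.36 in limb (random -0.04 to 0.00), with 143 of 523 detected at least 2-fold higher and 10 lower. Leaving out the REST-target list, the limb median was 0.32, with 109 of 482 at least 2-fold higher. Brain-enriched genes, REST-target members included, made up 30.9% of the genes higher in CKO limb, against 2.83% of all genes compared. Limb-enriched genes had a median of 0.41 in brain (random 0.00 to 0.01), with 69 of 420 at least 2-fold higher and 1 lower, and made up 26.5% of the genes higher in CKO brain, against 2.22% of all genes compared. In brain, brain-enriched genes had a median of -0.01, and in limb, limb-enriched genes one of -0.10.

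Genes higher in both tissues by at least 2-fold numbered 28 among 17409 compared in both, where independence would give 4.75. They included Lrp11, Ptprn, Col5a3, the dopamine receptor gene Drd2 and the granulocyte genes S100a8, S100a9 and Mpo. Genes lower in both numbered 11, where independence would give 0.957, and included Col1a1 and the zinc-finger gene Zfp429. Across these 17409 genes, limb and brain differences had a Pearson correlation of 0.13 and a Spearman correlation of 0.22; genes are not independent replicates. In a limma fit of genotype with tissue as a block, over 15630 genes measured on all 4 arrays, none passed an adjusted p of 0.05, and the smallest adjusted p was 0.667; 978 genes (6.26%) had an unadjusted p under 0.05. That fit takes a difference between tissues as error and has 1 residual degree of freedom. Rest, represented there by the probe from 77715162, the one with the smallest differences, had a mean difference of -1.46 log2, lower in CKO in both tissues, with a limma adjusted p of 0.667. More probes were above background on CKO arrays alone than on WT arrays alone, 2680 against 240 in limb and 2651 against 205 in brain. Counting just the probes above the pair's higher floor, the numbers were 1238 against 238 and 1144 against 205.

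**Figure D3:**
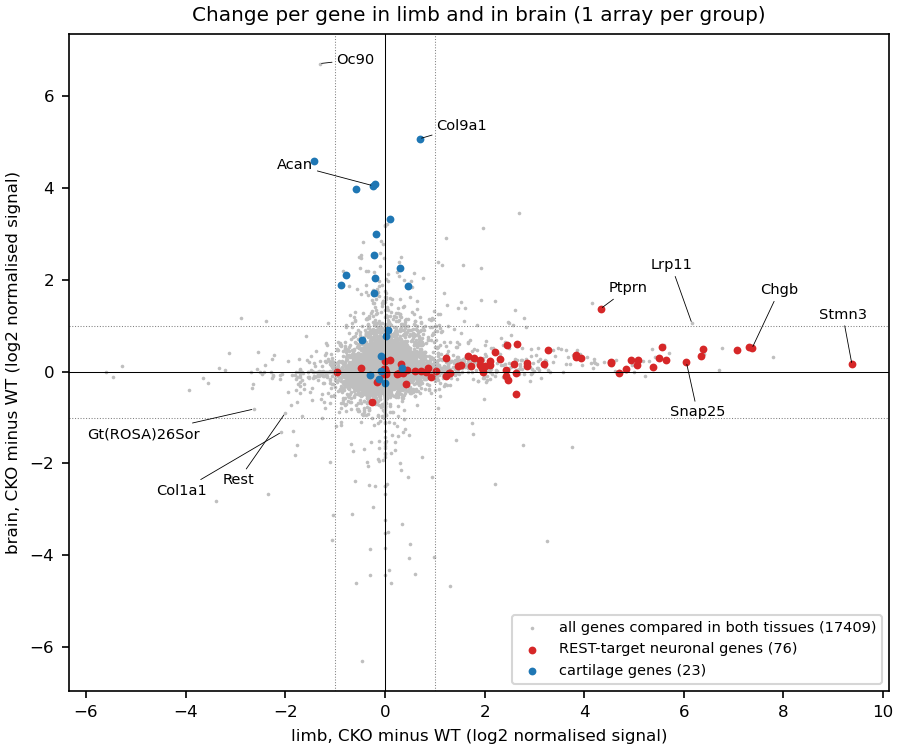
Log2 difference of CKO against WT in limb (horizontal) and brain (vertical) for 17409 genes compared in both tissues, with 1 array per group. REST-target neuronal genes (76) lie to the right along the horizontal axis, cartilage genes upward along the vertical axis, and Rest, Col1a1 and Gt(ROSA)26Sor at lower left.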

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

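All tests of explanations in this part were chosen after the results had been seen. Effects of opposite direction in limb and brain drew attention where both lay outside the range of random lists and exceeded the technical SD of a difference, or, for single genes, where both were at least 2-fold. With 1 array per group the difference between tissues was not tested. Cartilage genes differed by -0.14 log2 in limb and 1.95 in brain, and Oc90 by -1.31 in limb and 6.71 in brain. Tendon and connective tissue genes differed by -0.21 in limb and 0.78 in brain. Limb patterning genes differed by -0.21 in limb and 0.18 in brain, and macrophage and microglia genes by -0.21 in limb and 0.23 in brain. GABAergic neuron genes differed by 0.16 in limb and -0.19 in brain, but the limb sign turned with detection on both arrays and with the mean of all probes. Prap1, a gene of uterine and gut epithelium, differed by -2.90 in limb and 1.16 in brain.

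REST-target neuronal genes were higher in CKO limb, and carry-over of neural tissue into that sample is a candidate source. To reach their CKO limb levels by admixture, 55 REST-target genes would need a median of 21.5% of WT brain RNA (quartiles 3.60 and 46.6), whereas 18 neuronal markers outside the list would need 0.721% (quartiles 0.252 and 1.82), which argues against neural tissue as the source of the pattern though not against a trace of it. Scaling, background correction or filtering could not account for it either, since the lowest median over the settings was 1.59 log2. Among brain-enriched genes in limb, the 41 REST-target members had a median of 2.63, above an upper limit of 0.75 for random lists of other brain-enriched genes, which is consistent with loss of REST in limb cells. This remains a hypothesis from 1 sample per group, and which limb cells carry these transcripts stays open.

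Cartilage genes were higher in CKO brain, and inner ear and skull tissue left on that brain at dissection is a candidate explanation. Inner ear genes other than Oc90, Otor and Tectb, which had been seen first, had a median of 0.56 in 13 detected members, above the random limit of 0.095. Connective tissue genes had one of 0.78. Other lists did not share the rise: bone and joint genes had a median of 0.02, inside the random range of -0.08 to 0.12, and peripheral sensory ganglion genes one of -1.43. Col1a1, abundant in skull, was at -1.32, but it was also lower in CKO limb (-2.08), so its fall does not measure skull content. The skeletal factor Nkx3-2 was at least 79.1-fold lower. It was at 0.12 in WT brain against -3.37 in WT limb, so an outlying spot on the WT brain array cannot be told from expression. A lower share of neural tissue alone would raise other cell types alike, yet the cartilage median exceeded the endothelial median by 1.70. An effect of Rest loss on cartilage genes was not seen in limb (-0.14) but cannot be told apart from dissection in brain, where no value excludes it.

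Gt(ROSA)26Sor and Col1a1 were lower in CKO limb and CKO brain alike. A faulty spot is unlikely, since the smallest difference over the 4 probes and both tissues was -0.81 log2. Fewer collagen-producing cells would lower Col1a2 as well, which was at 1.07 in CKO brain; in CKO limb it was at -0.21, and -0.48 at its second probe, against -2.08 for Col1a1. Alleles inserted at these loci in CKO embryos may be involved, but the neighbouring genes do not decide it: their median was -0.060 over both loci and tissues, yet on 1 side of Col1a1 Ppp1r9b (-1.10 in limb, -0.24 in brain) and Samd14 (-0.45 and -0.16) were lower, and beside Gt(ROSA)26Sor Lhfpl4 was at 4.13 in limb. The labels mention doxycycline-inducible Cre alleles but name no locus, which keeps this open.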

How the results depend on the processing

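Normexp, quantile normalization and the other settings named for the processing were fixed before the data were examined; the common floor, support by another probe and the limma fit with tissue as a block were chosen after they had been seen. No setting turned the direction of a main result, and quantile normalization, the percentile over probes detected on all arrays, the series table and the common floor moved no count of genes by over 1.5 times; the common floor was run on those counts alone. The REST-target median in limb lay between 2.05 and 2.10 with the first 3 of these. No scaling moved the median of all genes by over 0.1 log2. Against 463 genes higher and 396 lower in CKO limb, normexp gave 287 and 148, detection on both arrays 264 and 216, no filter 938 and 900, a 1.5-fold threshold 887 and 869, a 3-fold threshold 285 and 165, and support by another probe 101 and 12. Against 260 higher and 231 lower in CKO brain, the same settings gave 88 and 113, 151 and 87, 722 and 668, 665 and 373, 107 and 151, and 24 and 5. Stricter filters, thresholds and support count fewer genes by construction; for normexp the cause was not tested. The REST-target median in limb (2.06) was 1.59 with normexp, 1.73 with detection on both arrays and on all 4, and 1.79 with the mean of all probes, and limb minus brain (1.88) was 1.43, 1.501, 1.501 and 1.55. Brain-enriched genes in limb (0.36) had 0.23 with normexp, 0.23 at 4-fold enrichment and 0.52 at 16-fold; limb-enriched genes in brain (0.41) had 0.26 with normexp and 0.30 at 4-fold. The correlation across genes (0.13) was 0.22 with normexp, 0.16 with detection on both arrays, 0.25 with no filter and 0.15 with the mean of all probes. Rest (-2.005 in limb, -0.91 in brain) was at -3.36 and -3.14 with the mean of all probes and at -0.80 in brain with normexp. Reversed medians were GABAergic genes in limb (0.16; -0.059 with detection on both arrays, -0.017 with the mean of all probes), Schwann cell genes in brain (0.14; -0.057 with the mean of all probes) and erythroid genes in brain (0.08; -0.094 with normexp, -0.027 with quantile normalization); the cause was not tested. Of the named genes' values, 877 stayed within the technical SD of a difference and 196 moved beyond it, 119 of them with normexp. Eda2r in limb (0.69) changed sign, to -0.056, with the mean of all probes. Signals near background limit the fold of dim genes, whose bounds depend on each array's floor (-4.95 for WT limb, -5.76 for CKO limb, -5.36 for WT brain, -6.19 for CKO brain). The slide could not serve as a block, since 1 slide held all 4 arrays with 1 per group; leaving out a sample was not possible, and the motif list was not run. No pairing by embryo or litter was possible because the labels number neither; tissue served as the block of the limma fit.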

Other observations

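Peripheral sensory ganglion genes were lower in CKO brain as a group, in a list written after 4 of its members had been seen. The median of its 17 detected members was -1.43 log2, against -0.09 to 0.14 for random lists, with 9 at least 2-fold lower and 0 higher. Leaving out those 4, the median of 13 members was -0.81, with 5 at least 2-fold lower. The ATP-gated channel of pain-sensing neurons P2rx3 differed by -2.05, and the transcription factors Isl2 and Hmx1, active in cranial sensory ganglia, by -1.68 and -1.64. In limb the same list had a median of -0.03 in 11 detected members, inside its random range, with 3 at least 2-fold higher, 0 lower, an upper quartile of 1.18 and a mean of 0.63, opposite in sign to the median. The inner ear list, also written afterwards, had a median of 0.65 in brain over 16 detected members, with 6 at least 2-fold higher and 0 lower, and of -0.14 in limb over 14, inside its random range, with 1 at least 2-fold higher and 1 lower.

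Genes next to Rest on chromosome 5 were mostly near 0. The exceptions above 0.5 log2 in size were Polr2b (0.73), Spink2 (0.63), Igfbp7 (-0.57) and Noa1 (-0.50) in limb and Adgrl3 (-0.67) in brain, and Noa1, the next measured gene beyond Rest, was at -0.46 in brain. Among 13542 genes with a current symbol that were measured on all 4 arrays, 20 were at least 1.5-fold lower in both tissues, where independence would give 1.84, and in 19 of them any other probe measured on both arrays of a tissue was lower there too. Those included Rest, Col1a1, Gt(ROSA)26Sor, Zfp429 (-1.86 in limb, -1.28 in brain), the mast cell protease Cma1 (-1.67 and -0.96) and Cited4 (-0.89 and -1.17). Of 30 fixed lists, 10 had a median above and 10 below their random range in limb, and 12 above and 6 below in brain. Of 30 lists of randomly drawn genes, 1.5 would lie outside in each tissue. The fixed lists were not random draws and each group had 1 array, so these counts are not a test.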
